A study of Mus musculus with 2 samples.

How the data were processed

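Total RNA from the skin of 25-day-old mice was labelled with Cy3 or Cy5, from 500 ng, and hybridised to 2 Agilent mouse arrays, per the labels' protocols. Each array carried transgenic RNA against control RNA, pooled from 4 mice per genotype, with the dyes exchanged between the arrays.

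The deposited scanner output of array 1 gives spot intensity values in 2 channels. Per the file headers, Agilent Feature Extraction 9.5.1.1 subtracted the background from each intensity, removed spatial trends, normalised the dyes by a linear and a LOWESS step and replaced dim values by surrogates. Such surrogates compress ratios near background. The deposited log10 ratio of Cy5 over Cy3 and its error come from the same program, per the file headers. Its deposited p-value, per the file headers, comes from an error model of the spot on 1 array and is no test across mice. The scanner output of array 2 was not used here. The deposited value table holds 1 log10 column per array. For array 1 it matched log10 of Cy5 over Cy3 processed signals at all 43790 features, within 1e-08. For array 2 the scale and direction were settled from the data. As deposited, the columns correlated at -0.579 over 41534 features that are not controls, the sign of a dye exchange left unturned. The 10 spike-in probes follow the dye and correlated at 1.00 with a slope of 1.00. The medians of the columns were 0.0145 and -0.0243, so neither column had been centred on its median. The steps after Feature Extraction are not given in the sources used here.

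Each column was converted to log2, and array 2 was turned so that values are transgenic over control. The main value was the mean of the 2 arrays. Control spots and 29 spots flagged as outliers on array 1 were left out, and spots of a probe were averaged. Probes entered if well above background in at least 1 channel of array 1. The probe with the highest signal stood for a gene, and among 2360 genes with several such probes, 24 had probes that differed by over 2-fold. On array 1 no spot other than controls (0) was saturated, so leaving saturated spots of that array out changes nothing. Saturation on array 2 was not checked. Array signal was low. The median net signal per the file header was 55.1 in Cy3 and 41.7 in Cy5, beside mean local backgrounds of 35.7 and 35.4. The lowest processed signals well above background were 199 (Cy3) and 190 (Cy5). Processed signals are after dye normalisation, so they cannot be set directly against the net signals and backgrounds of the header. For a probe dim in 1 channel of array 1, a bound was computed as the bright signal over the higher of that lowest signal and the probe's own. Where the probe's own signal is the higher, this is the measured ratio and no lower bound. The bound rests on 1 array and is open to dye bias. Some dim probes had signals above that lowest signal, such as Folr2 at 269 in Cy3 and Krt34 at 240 in Cy5. A fold given as "at least" therefore assumes that lowest signal for the dim channel and is no strict limit. Over 10 probes printed 10 times, with no flagged spot and well above background in both channels, the median standard deviation of the log2 ratio was 0.09 on array 1 and 0.10 on array 2. The number of arrays limits the precision. With 1 array per dye orientation, slide and scan date could not be tested as batches.

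Probes were named through a RefSeq gene table of assembly GRCm38.p6 by accession (24485 probes), symbol (6233) or synonym (2390), and 8059 kept the array's name. Coordinates are those of the array design, on mm8 per the file header.

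The labels do not say that the arrays carried separate pools, so no biological replicate was counted. Genes were called by size: at least 2-fold the same way on each array. Gene lists, fixed before the data were examined, were described by their median and its percentile among 10000 random lists of equal size matched on signal in 20 bins, and stand apart below the 2.5th or above the 97.5th percentile. These describe the 2 pools only. Genes named are Pla2g2f, the 12 highest and 12 lowest that carry a symbol and pass the rule, and members with the largest absolute means from each list, up to 4. Other list members in the text were chosen after their values were seen. Values of some single genes are not reported here.

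The size rule and list percentiles were tested on simulated data, in which 200 of 10451 genes were changed and the differences between the arrays served as noise. The rule recovered 38 of 40 genes changed 3-fold and 40 of 40 changed 4-fold. It recovered 3 of 40 changed 2-fold and 0 of 40 changed 1.5-fold, and called 0 of 10251 unchanged genes. The noise on array 2 was entered with the opposite sign on array 1, so an unchanged gene could hardly pass the same way on both. The 0 is therefore no error rate of the rule. That opposite noise also lowers the recovery of genes changed exactly 2-fold, so 3 of 40 is no measure of sensitivity there. Of 200 unchanged lists of 15 genes, 11 stood apart. These lists were drawn at random, so about that share was set by the percentile limits. It does not cover lists whose genes vary together. In the data, of 30 lists with a measured member, 15 lay above the 97.5th percentile and 6 below the 2.5th.

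Alternatives covered each array alone, array 1 recomputed from the scanner file with limma 3.58.1 (normexp with an offset of 50, or no background correction, with or without loess), Agilent's own log ratio, centring on the median, the median of a gene's probes, other filters on dim probes, thresholds of 1.5-fold and 3-fold, 2-fold in the mean, an added Agilent p under 0.01, and random lists matched in 10 bins or unmatched. Centring on spike-ins, by the same mean offset of 0.47 taken from both arrays, and raising dim channels of array 1 to the lowest signal well above background were chosen after seeing the data. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.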

Results

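RNA from the skin of 25-day-old Pla2g2f-transgenic mice was compared with that of littermate controls on 2 two-colour arrays. Pla2g2f encodes a secreted phospholipase A2, an enzyme that releases fatty acids and lysophospholipids from phospholipids. Both genotypes had a C57BL/6 background, and RNA from 4 mice was pooled for each genotype. The transgenic pool was labelled with Cy5 on array 1 and with Cy3 on array 2. The labels do not say that the arrays carried separate pools, so the arrays were averaged as 1 replicate, and no p-value across mice can be given. The spread beside a value is the difference between the 2 arrays, which is technical. Of 41167 probes, 13335 were well above background in at least 1 channel of array 1, and these stood for 10451 genes or transcripts. Across those probes, which are not independent replicates, the log2 ratios of the 2 arrays correlated with a Pearson r of 0.777 and a Spearman rho of 0.588. The median absolute difference between the arrays was 0.23 on the log2 scale.

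The comparison asked which transcripts differed in skin that, per the title of the series, shows hair loss and a psoriasis-like thickening of the epidermis. The lists of hyperproliferation keratins and alarmins, sebaceous lipid genes and cornified envelope genes had medians above those of random lists, with 8 of 12, 12 of 14 and 13 of 32 members higher in the transgenic pool. Those of hair keratins, keratin-associated proteins and the inner root sheath had medians below, with 10 of 10, 31 of 32 and 9 of 9 members lower. At least 2-fold differences on each array were found for 389 genes that were higher and 176 that were lower. No gene (0) was 2-fold apart in opposite directions on the 2 arrays. The calls depended on the scale. The spike-in control RNAs lay 0.47 log2 units higher against the transgenic pool, and centring on them, an alternative chosen after seeing the data, gave 173 higher and 472 lower genes. The share of higher genes among all calls was then 26.8%, against 68.8% in the main setting. All values below are relative to the arrays' own scaling, in which the median gene lay at -0.0080.

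**Figure D1:**
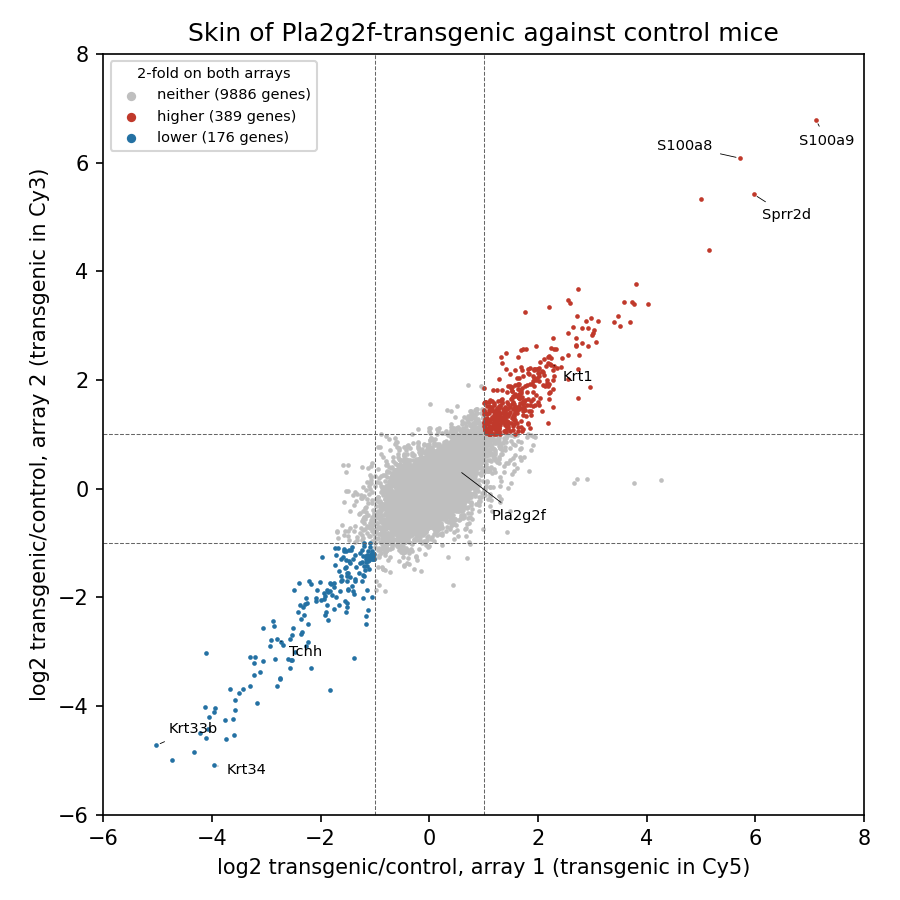
Each point is 1 of 10451 genes, with log2 transgenic over control on array 1 (x axis) and on array 2 (y axis), and dashed lines at 2-fold. The 389 higher genes (red) and 176 lower genes (blue) lie along the diagonal, with S100a9 at 7.12 and 6.78, while Pla2g2f lies at 0.54 and 0.34 under the arrays' own scaling and its mean at -0.030 when centred on spike-ins.

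The transgene itself was first examined as a check of the labels. The probe for Pla2g2f (NM_012045; mm8, chromosome 4, 138022707 to 138022766) was well above background in both channels of array 1. Its log2 ratio was 0.54 on array 1 and 0.34 on array 2, a mean 1.36-fold ratio, which did not pass the size rule and became -0.030 with the arrays centred on the spike-ins. Whether the transcribed part of the transgene contains this probe is not given in the sources used here. Of the 10 other secreted phospholipase A2 genes on the list, 1 was measured, Pla2g12a, with a mean log2 ratio of 0.50, and its 2 probes spanned values down to 0.06. Without the filter on dim probes the median of the secreted phospholipase A2 list (secreted PLA2 family other than the transgene) turned to -0.028 over 10 members, at the 1.61th percentile, and the list stood apart on the low side, mostly through probes not well above background in either channel.

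Genes of wounded or psoriasis-like epidermis had a median log2 ratio of 2.53 over 12 measured members, at the 100th percentile of 10000 random lists matched on signal. The rule was passed by 8 members, all higher. S100a9 (NM_009114; mm8, chromosome 3, 90778590 to 90778649), a subunit of the alarmin calprotectin, rose 124-fold, with log2 ratios of 7.12 and 6.78. Its partner S100a8 had a mean log2 ratio of 5.90. S100a8 was not well above background in the control channel of array 1. It was at least 26.4-fold higher there, if the control is set to the lowest signal well above background. Stfa2 and Stfa3, which encode inhibitors of cysteine proteases, had mean log2 ratios of 5.17 and 4.77, Stfa2 being dim in the control channel of array 1 and at least 18.4-fold higher there, and Krt16, a keratin of activated epidermis, rose 10.4-fold. The serpin Serpinb3b had a mean log2 ratio of 3.79 and was at least 9.63-fold higher on array 1. The remaining 4 members did not pass: Krt6a lay at 0.53, Krt17 at 0.07, Krt6b at -0.07 and Arg1, dim in the transgenic channel of array 1, at -1.09. Without the filter on dim probes the median was 1.43 over 18 members. The stefin and serpin genes have close copies whose transcripts one probe can share, so values of single members are uncertain. Skin RNA does not tell which cells, in the epidermis or outside it, carry the transcripts of this list.

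Cornified envelope genes, whose proteins build the outermost layer of the epidermis, had a median log2 ratio of 0.86 over 32 measured members, at the 100th percentile. Of these, 13 were higher by the rule, 0 were lower and 19 did not pass. Below 0 on both arrays were 4 members. Sprr2d had a mean log2 ratio of 5.70 (at least 25.1-fold higher on array 1), Lce3f one of 3.09 (at least 4.04-fold) and Lce1g rose 6.54-fold. The Sprr2 and Lce1 genes are near-identical families, so the probe of 1 gene can report another. The epidermal lipid barrier list had a median of 0.54 over 14 members, at the 99.96th percentile, and 4 were higher, among them Elovl4, an elongase of very long fatty acids, at 5.40-fold. Without the filter on dim probes its median was 0.20, and centred on the spike-ins it was 0.07. Among suprabasal keratinocyte genes the median was 0.54 over 12 members (99.97th percentile), but only 1 passed the rule, Krt1, which rose 4.79-fold. Centred on the spike-ins the suprabasal median was 0.07. Basal keratinocyte genes had a median of 0.16, which turned to -0.30 when centred on the spike-ins, and lay within the random range at the 92.0th percentile. From array 2 alone the median of the basal keratinocyte list was 0.29, at the 98.3th percentile, and the list stood apart. Krt14 alone passed, at 2.17-fold.

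Other genes with measured means among the 12 highest were Cxcr6, a chemokine receptor of T cells, with a mean log2 ratio of 3.71, Cd163l1 at 3.59, Cstdc6 at 3.58, Csta2 at 3.33 and the beta-defensin Defb6 at 3.51. Cxcr6 and Cd163l1 were not well above background in the control channel of array 1, where they were at least 7.5-fold and 8.73-fold higher, so the places of these and other dim genes among the 12 highest are uncertain. The 3 probes of Cstdc6 ranged from 3.58 to 4.89.

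Hair keratins and keratin-associated genes made up the 12 lowest named genes. The order of those dim in the transgenic channel of array 1 is uncertain. All 10 measured hair keratins were lower by the rule, with a median log2 ratio of -3.17, at the 0th percentile of random lists (0 of the random medians lay below it). Krt33b (XM_981536; mm8, chromosome 11, 99839830 to 99839889) lay at -5.02 and -4.72 on the 2 arrays, although its other probe gave -1.68. Krt33a had a mean of -4.87. Krt34, not well above background in the transgenic channel of array 1, was 15.6-fold lower there as measured, with a mean of -4.53. Its own dim signal exceeded the lowest signal well above background, so this is no lower bound. Of 32 measured keratin-associated genes, whose proteins crosslink the keratins of the hair shaft, 31 were lower, with a median of -3.14. Krtap6-1, Krtap22-2 and Krtap21-1 had measured means of -4.36, -4.35 and -4.18, and their transgenic channel was dim on array 1. There Krtap22-2 and Krtap21-1 were at least 11.2-fold and 8.23-fold lower. Krtap6-1 was 18.7-fold lower there as measured, which is also no lower bound. The probes of Krtap3-1, at least 16.6-fold lower on array 1 by its brightest probe, ranged from -4.08 to -0.81 and those of Krtap16-3 from -4.04 to -1.18, and members of this family share sequence. Krtap17-1, well above background in both channels, had a mean of -3.99. Krtap6-5, Krtap19-9b and Krtap14, dim in the transgenic channel of array 1, were at least 8.61-fold, 6.66-fold and 5.85-fold lower there, with measured means of -4.13, -4.01 and -3.83.

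The inner root sheath, which surrounds the growing hair, followed. All 9 measured members were lower, with a median of -2.67. Tchh, which encodes trichohyalin, had a mean of -2.79, and its second probe gave -1.93. Padi3 lay at -2.85. Krt26, dim in the transgenic channel of array 1, was at least 6.51-fold lower there, with a measured mean of -3.73. Among regulators of the hair matrix, 7 of 14 measured members were lower and 7 did not pass, with a median of -1.10. The transcription factors Msx2 and Lef1 had means of -2.01 and -1.65. Hoxc13 lay at -1.68 but was not well above background in the transgenic channel of array 1. The bound there was 1.28-fold lower, but its control signal of 243 was close to the dim signal of Krt34, 240. A decrease on array 1 is therefore uncertain. Pigment cell genes had a median of -1.40, with 7 of 10 members lower, Trpm1 at -1.85 among them. Gpnmb, dim in the transgenic channel of array 1, was at least 5.18-fold lower there, with a measured mean of -2.07. Genes of hair follicle stem cells and outer root sheath had a median of 0.51 over 9 members (99.8th percentile), of which 5 were above 0 and 4 below 0 on both arrays, and 1 passed, Krt75, with a mean of -1.78. Without the filter on dim probes this list's median was 0.09 and no longer stood apart, and centred on the spike-ins the median was 0.04.

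Cell division genes had a median of -0.39 over 26 measured members, at the 0th percentile, and 25 of them were below 0 on both arrays. None (0) passed the size rule: the mean log2 ratio was -0.92 for Cdk1, -0.89 for Kif11 and -0.68 for Top2a. Skin RNA does not tell whether these transcripts were lower in cells of the hair follicle, the epidermis or elsewhere.

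Sebaceous gland and sebum lipid genes had a median of 1.65 over 14 measured members, at the 100th percentile, and 12 passed the rule, all higher. Fa2h, a fatty acid hydroxylase, rose 6.69-fold, Cidea, a lipid droplet protein, 5.39-fold, and Soat1, which esterifies cholesterol, 4.74-fold. Adipocyte genes had a median of 1.37 over 10 members, and 7 were higher, including Cfd at 4.22-fold and Fabp4 at 2.93-fold. Both lists hold lipid genes, and whether sebaceous or fat cells carry the rise was not tested. Skeletal muscle genes had a median of 0.02 over 15 members, at the 59.1th percentile, which turned to -0.45 when centred on the spike-ins. Myh2 rose 2.54-fold and Myh1 2.5-fold, and the 13 others did not pass.

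Macrophage genes had a median of 1.04 over 9 measured members, of which 4 were higher, with Adgre1 at 2.48-fold and Lyz2 at 2.35-fold. Langerhans and dendritic cell genes had a median of 1.27 over 6 members, and 4 were higher: the antigen presentation genes H2-Eb1 at 2.83-fold, H2-DMb1 at 2.73-fold and H2-Ab1 at 2.68-fold, and Cd74 at 2.17-fold. Both lists lay at the 100th percentile. Centred on the spike-ins their medians were 0.57 and 0.80, and their higher genes no longer passed the rule. Mast cell genes had a median of 0.90 over 4 members (99.4th percentile), of which 1 was higher, Hdc, at 3.19-fold in the mean and at least 1.55-fold on array 1. The T cell list had 2 measured members and a median of 0.70, at the 85.5th percentile. Without the filter on dim probes 13 members of the T cell list had a median of 0.33, at the 99.98th percentile, and the list stood apart. None (0) of the 12 listed neutrophil genes with a probe named here was well above background, so neutrophils could not be assessed at this signal. Interferon response genes had a median of 1.23 over 3 measured members (99.7th percentile), of which 2 passed, Ifit3 and Oasl2. Both were dim in the control channel of array 1. With dim probes kept, the median of the interferon response list fell to 0.48 over 16 members, at the 100th percentile, and the list stood apart. With probes well above background in both channels 1 member was left and the list no longer stood apart.

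Cytokines and chemokines of inflamed skin had 4 of 26 listed genes measured, with a median of 0.53 at the 95.9th percentile, within the random range. From array 1 alone the median was 0.75, and the list stood apart. With dim probes kept, the median of this list (IL-17, IL-36 and IL-20 family cytokines and chemokines) was 0.13 over 22 members, within the random range. Ccl2, a chemokine that attracts monocytes, passed at 3.62-fold in the mean and at least 1.78-fold on array 1. Enzymes and receptors of lipid mediators had a median of -0.01 over 16 measured members, at the 49.1th percentile. Ltc4s, the leukotriene C4 synthase, was higher at 3.33-fold in the mean but, dim in the control channel of array 1, at least 1.57-fold there, and Ptgds, a prostaglandin D2 synthase, was lower at -1.17. The remaining 14 did not pass, Alox5ap at 1.07 and Alox12e at 0.95 among them. EGF receptor ligands and shedding genes had a median of -0.02 over 7 members (47.1th percentile), with Areg at a measured mean of -1.13. Areg was dim in the transgenic channel of array 1, where it was at least 1.89-fold lower.

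Among other lists, endothelial genes had a median of 0.64 over 7 members (99.9th percentile), 0.17 when centred on the spike-ins, with Vwf higher at 2.11-fold. Erythroid genes had a median of 0.96 over 4 members (99.8th percentile), none (0) of which passed on both arrays. Fibroblast and matrix genes lay at 0.42 over 15 members (99.9th percentile) and circadian clock genes at 0.43 over 10 (99.4th percentile), and both medians turned below 0 when centred on the spike-ins, to -0.050 and -0.034. Housekeeping genes had a median of 0.15 over 13 members, -0.32 when centred on the spike-ins, at the 90.8th percentile, with B2m higher at 2.57-fold. Sex-specific genes had a median of -0.22 over 3 members (14.1th percentile), with Xist at -0.22, Ddx3y at 0.28 and Eif2s3y at -0.36. The sex-specific median was 0.14 on array 1 and -0.31 on array 2, and Eif2s3y was 0.14 and -0.86, so the arrays disagree on the sign of both.

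**Figure D2:**
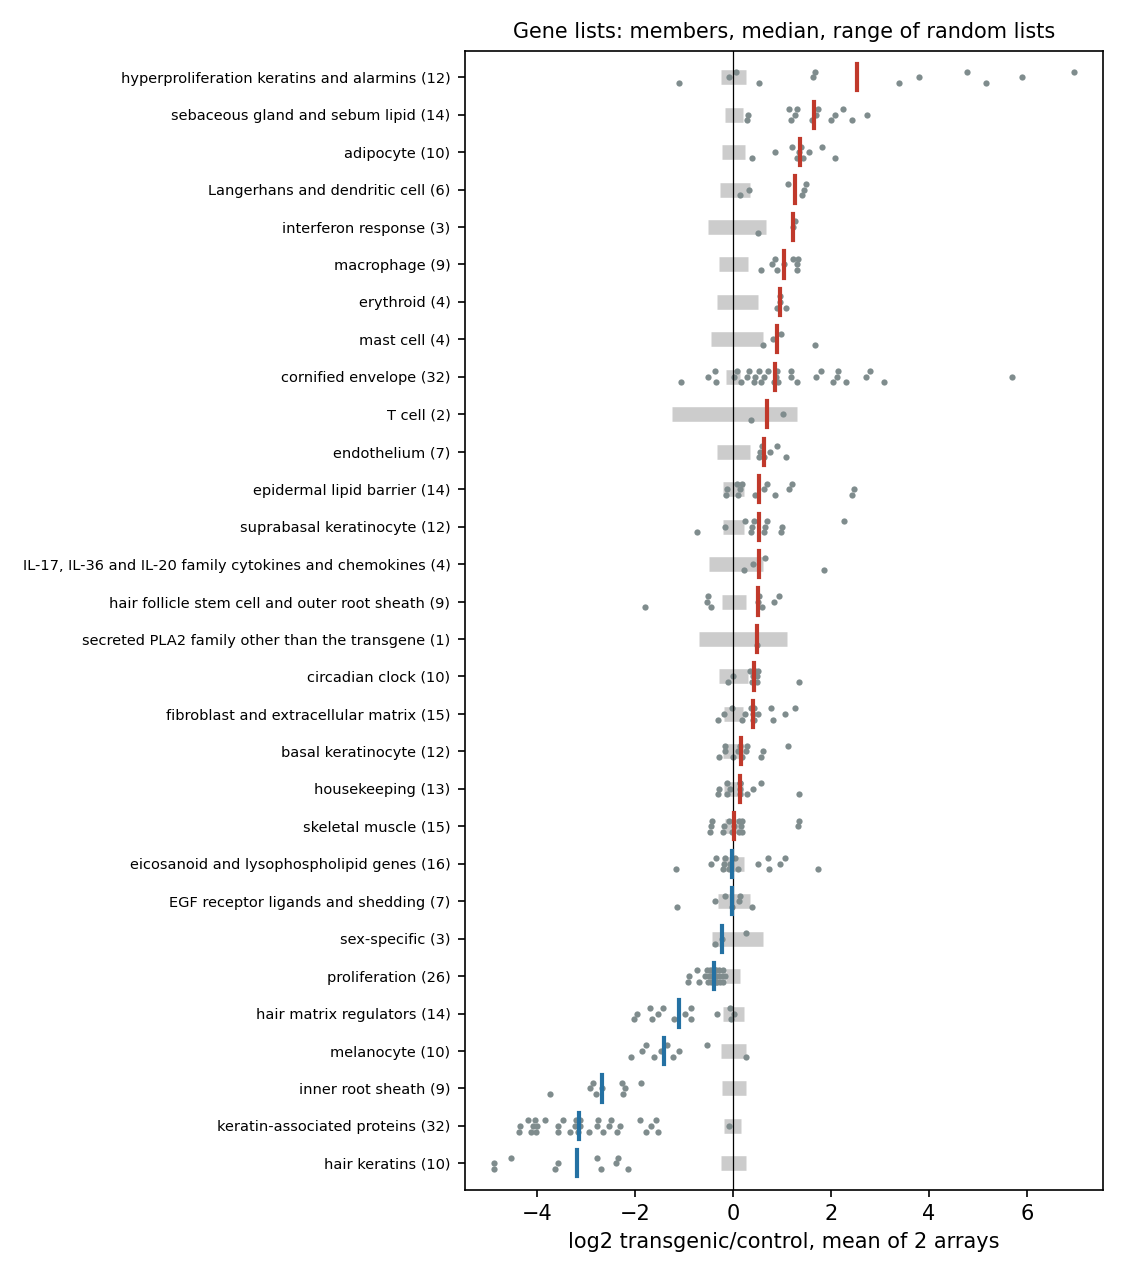
Each row is a gene list with its number of measured members, grey points are members (mean log2 transgenic over control of 2 arrays), coloured bars are list medians and grey bands are the range of random list medians between the lower and upper limits. Hair keratins lie lowest at -3.17 and hyperproliferation keratins and alarmins highest at 2.53. Fibroblast, circadian, basal keratinocyte, housekeeping and skeletal muscle medians lie above 0 here but below 0 when centred on the spike-ins.

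Of the 389 higher genes, 146 were not well above background in the control channel of array 1, and of the 176 lower genes, 90 were not in the transgenic channel, so that their measured ratios rest on 1 dim channel. With array 1 taken from the scanner file with normexp background correction and loess, the counts were 107 higher and 56 lower, all among the main calls. This setting lowered the median of the hyperproliferation list from 2.53 to 1.77 and that of the lipid barrier list from 0.54 to 0.34. It moved the keratin-associated median from -3.14 to -2.14 and the hair keratin median from -3.17 to -2.35. The interferon response median fell from 1.23 to 0.73. All these lists still stood apart.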

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

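The tests of the spike-ins were chosen after their values were seen. Spike-in RNAs, which no planned comparison of the 2 genotypes uses, did not keep the same level against both pools. With each array turned to transgenic over control, the 10 spike-in probes lay 0.47 log2 units above the arrays' own genes, a 1.38-fold offset, with a standard deviation of 0.03 over probes and a range of 0.44 to 0.51. A dye effect cancels in this turned value, and an offset of 0.47 with one sign for all probes argues against it. A candidate explanation is a smaller amount of messenger RNA per total RNA in the transgenic pool. Unequal addition of spike-ins on 1 array alone would leave the other array without an offset. The offset was 0.55 on array 1, from the fit to expected ratios in the file header, and by difference 0.39 on array 2. The residual standard deviation of the fit was 0.23. A dye effect cancels only in the mean of the arrays and can shift this split. An offset of 0.94 on 1 array alone, together with a dye effect, would give the same values. Unequal addition on 1 array alone is therefore not excluded. Unequal addition alike on both arrays would give the same 1.38-fold factor for every gene, so this and less messenger RNA cannot be told apart here.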

How the results depend on the processing

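Signal over background limits these results, since the median net signal was 55.1 in Cy3. Each array set transgenic against control RNA, so each ratio was already paired within its array. Both arrays were averaged as 1 replicate and no test was made. From 1 array alone the higher count ranged from 520 to 567 and the lower count from 259 to 273. With array 1 from the scanner file, higher and lower counts were 107 and 56 (normexp and loess), 132 and 53 (normexp, median centred, no loess) and 122 and 60 (no background correction, loess). With normexp the counts fell both with and without loess, so loess alone does not account for the drop. The cause was otherwise not tested. Probes well above background in both channels gave 243 and 86, as fewer genes were tested. By construction, 1.5-fold gave 863 and 396 and 3-fold 140 and 95. Centring on spike-ins, chosen after seeing the data, gave 173 and 472, since every gene moved by the same 0.47. Counts under the other alternatives stayed within 1.5 times of the main ones. Without the filter on dim probes, array correlation was 0.575 and the median of the secreted phospholipase A2 list was -0.028, apart on the low side, as more probes entered. Pla2g2f was 0.29 with normexp and loess, 0.30 with normexp, median centred without loess, and -0.030 centred on spike-ins. The cytokine list, at 0.34 to 0.75 from 1 array alone, passed the upper limit on array 1 alone and, at 0.53, with random lists not matched on signal. The cause was not tested. Centred on spike-ins, the fibroblast and circadian medians turned to -0.050 and -0.034. Of 419 gene list values under the alternatives, 410 kept their call. Centring on the median or the spike-ins shifts every gene alike, so it could not change a list's percentile. Agilent's own log ratio gave the deposited values again. This count therefore overstates how far the lists were tested. For the named genes, 1226 values kept theirs or moved by less than the spread between arrays, 109 lost the size rule, 19 gained it and 117 moved without a call.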

Other observations

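The tests of sterol synthesis, fatty acid oxidation, eosinophil and innate-like T cell genes were chosen before their values were seen, after single related genes had been seen among the higher ones. All other tests here were chosen after the result was seen. Cholesterol synthesis genes were higher as a group. Over 18 measured genes the median was 0.73, at the 100th percentile of random lists, and 15 were above 0 on both arrays. By the size rule 4 were higher and 14 did not pass, and Msmo1 lay at 2.0. Fatty acid oxidation genes, tested after Acot5, Aadac and Ces1f were seen, had a median of 0.69 over 18 genes, also at the 100th percentile. Only Pex11a, a peroxisomal membrane protein, passed, at 1.40. Both medians stay above 0 after the shift of 0.47 to the spike-in scale. None (0) of the genes on these 2 lists is on a list fixed earlier, although fat and sebaceous cells are known to express many of them.

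Cells behind some of the highest immune genes could not be identified. After Rnase2a, at 2.74 and dim in the control channel of array 1, was seen, 1 other gene of the eosinophil list was measured, the attractant Ccl11, also dim there, at 1.60, which is too few. After Cxcr6, Cd163l1 and Ltb, 4 other genes of innate-like T cells (Rora, Il1r1, Maf and Gata3) had a median of -0.29. That lies within the random range, but a minimum of 5 measured genes was set after this was seen, because these 4 are also expressed by other skin cells and can hide a small number of T cells.

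The lists of hair keratins, keratin-associated proteins, inner root sheath, hair matrix and pigment cells were lower. Genes of follicle stem cells and outer root sheath went both ways, 5 above 0 and 4 below 0 on both arrays. Cross-hybridisation within the keratin-associated family would leave single-copy regulators of the hair matrix near 0, and their median was -1.10, beyond the random range. A dye bias would change sign with the dyes, and the keratin-associated median was -2.97 or lower on each array. A smaller amount of hair-forming tissue or growth in the transgenic pool may account for the pattern, and pigment cell genes, which are active in growing follicles, were lower too, at -1.40. Whether this follows from the genotype, from the stage of the hair cycle or from the skin sampled stays open with arrays that count as 1 replicate.

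Markers of several other cell types were higher. A smaller share of hair transcripts alone would raise all other types alike, but the fat and muscle medians were 1.35 apart, beyond the spread of 0.55. A rise shared by all other genes would also include the median gene, which lay at -0.0080 under the arrays' own scaling. It could therefore not raise these lists above other genes. A scale set by less messenger RNA could raise these markers as well. Yet, centred on the spike-ins, the lowest of the fat, macrophage and antigen-presenting cell medians stayed at 0.57, beyond the random half-width of 0.31. The endothelial median fell to 0.17 on that scale. That is under 0.35, the upper limit of its random range on the arrays' own scale. Such limits and half-widths serve here as a spread around 0, not as random ranges on the spike-in scale. The fibroblast median fell to -0.050, so a rise against the spike-ins is not shown for either. For mast cells the value of 0.44 was within 0.53, so with 4 genes a rise against the spike-ins cannot be told from 0. Centring moves every gene alike, so it leaves the place of a list among random lists unchanged. That place stays at the 99.4th percentile for mast cells and at the 99.9th for endothelial genes. A scale effect alone thus does not set a list apart from other genes. More cells of the types whose markers were higher, more of their transcripts per cell, and differences in the skin sampled stay open as hypotheses.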
